A study of Rosa hybrid cultivar with 3 samples.

How the data were processed

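Transcript abundance was measured by sequencing total RNA from median nodes of a hybrid rose, the shrub cultivar Radrazz. Plants were grown in a glasshouse for 5 weeks after potting, and excised nodes were then kept for 1 day in vitro on agar medium. The medium held 100 mM sucrose, either with no nitrate or with 10 mM nitrate. Each library came from a pool of 30 nodes, per the labels' design text. RNA was purified on silica columns with DNase treatment, and libraries were built with an Agilent protocol for the Illumina MiSeq, per the labels' protocols.

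The series holds 3 samples, of which 2 are labelled as sucrose medium and 1 as sucrose with nitrate. Counts of 1 library per medium were analysed here. The other sucrose sample was not analysed here, as no counts for it were among the files used. The labels do not say whether it is a separate pool of nodes or another run of the same library. The labels pair no samples, and 1 analysed library per medium leaves no residual degrees of freedom, so no p-value is given anywhere.

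The deposited files hold raw read counts, 1 whole number for each reference sequence, with no normalization by the authors. They have 4 columns laid out as SAMtools idxstats writes them, which are the sequence identifier, its length in bases, the aligned reads and the unaligned reads. Bowtie 1.1.1, SAMtools 1.3.1 and edgeR 3.24.3 are named per the submitters' processing notes, without their roles. The origin of the reference set, the alignment settings, the treatment of reads that match several sequences and the use of strand are not given in the sources used here. Reads from near-identical sequences may therefore be split between them. Among sequences with at least 20 counts, 50.8% of the counts were even in each library, so reads were not counted in pairs falling on 1 sequence. The last line of each file names no sequence and holds the unaligned reads. It was kept out of library totals and ratios, and its share was 27.7% of all reads in the sucrose library and 20.7% in the nitrate library.

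The files do not pair the sequence identifiers with gene names or genome positions, and no table of names was used here. The 28 gene lists fixed before the data were examined, and the planned values for asparaginase and asparagine synthetase, were therefore not analysed here. For the same reason the naming rule, fixed at the same time, was the version for files without names. It prints by identifier the 2 sequences that ranked first as higher and the 2 that ranked first as lower with nitrate, ranked by the bound of the interval of the fold nearest to 1. Other sequences are described by length and count only.

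Library totals were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3. Per sequence, 0.5 was added to each count, and the log2 ratio of the nitrate over the sucrose library was taken after scaling. An exact (Clopper-Pearson) binomial 95% interval on the split of the reads between both libraries, rescaled by the same factor, gave the interval of the fold. Such intervals cover counting error only, not the spread between pools of nodes, and reads without molecular identifiers are not independent molecules. A sequence was called higher or lower when its ratio was at least 2-fold and its interval excluded 1, among sequences with a summed count of at least 20. This is a rule of size, not a test of the nitrate effect. A count of 0 was read against a floor of 3 counts, which is 0.900 CPM (counts scaled to the library total) in either library. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

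The procedure was tested on simulated data drawn from the mean share of each sequence with Poisson error. In a simulated nitrate against sucrose comparison with 28005 sequences tested, 200 sequences were given known ratios. Each ratio was given to 50 sequences. The rule recovered 52% of those with a true ratio of 2, 100% of those at 4, 100% of those at 8 and 84% of those at 0.25. Recovery at a true ratio of 2 is limited by the 2-fold threshold itself. Only nitrate counts were changed, so the summed count rose or fell with the ratio. Recovery at 4 and 0.25 therefore does not compare directions. The rule called 1.28% of the unchanged sequences. In 20 simulated pairs of libraries with no difference, the rule called a mean of 362.3 sequences, between 337 and 385, and these counts are set beside the observed ones.

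Alternatives fixed before the data were examined were other scalings (plain totals, DESeq2 1.42.0 median-of-ratios, upper quartile, and totals without the 100 most abundant sequences), other count filters, 2 added to each count, other fold thresholds, stricter intervals and thinning of the deeper library. Centring of ratios by length was added after the data were seen.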

Results

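Transcripts of rose median nodes were compared after 1 day on sucrose medium with and without nitrate, with 1 library of 30 pooled nodes per medium. A median node is a stem segment carrying an axillary bud, and the title of the study sets nitrate and sucrose supply against bud outgrowth. Reads had been aligned to 110110 reference sequences with a median length of 443 bases and a range of 201 to 10801 bases. The sucrose library held 3334591 aligned reads and the nitrate library 3334912. The unaligned share of all reads was 27.7% in the sucrose library (exact 95% interval 27.67 to 27.75) and 20.7% in the nitrate library (20.64 to 20.71). The aligned totals differed by 321 reads while all reads differed by 408811, and whether reads were removed before or after alignment is not given in the sources used here. The unaligned shares therefore describe the deposited counts, and may not be those of the full sequencing runs. A further sample labelled as sucrose medium was not analysed here. With 1 library analysed per medium, every difference below is between these libraries and has no replicate check.

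Both media gave transcript populations of similar breadth. A count was seen for 85672 sequences in the sucrose library and 85588 in the nitrate library, and 72480 of these were shared. No read fell on 11330 sequences in either library. Sequences seen in 1 library alone were thinly counted. Those seen in the sucrose library alone reached at most 19 counts and those seen in the nitrate library alone at most 22. Only 5 and 4 of them, respectively, had over 10 counts. Across the 27868 sequences with a summed count of at least 20, log2(CPM + 1), where CPM is counts scaled to the library total, correlated between the libraries with a Pearson r of 0.96 and a Spearman rho of 0.93. These are correlations across sequences, which are not independent replicates.

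The most abundant sequences were mostly shared at similar levels. Abundance here is the share of aligned reads, without correction for length. Long sequences collect more reads, so this does not rank numbers of transcript molecules. Of the 20 most abundant sequences, 18 lay within 1.5-fold between media. The most abundant, of 10801 bases, took 2.42% of aligned reads on sucrose (exact 95% interval 2.40 to 2.44) and 2.25% with nitrate (2.24 to 2.27). The second, of 5824 bases, was the only one of the 20 past the 2-fold rule. It took 1.18% of aligned reads on sucrose (1.17 to 1.19) and 0.493% with nitrate (0.486 to 0.501), a level 2.45-fold higher on sucrose (counting interval 2.41 to 2.49). The remaining sequence outside 1.5-fold had 1716 bases and was 1.69-fold higher with nitrate (1.63 to 1.77), short of the rule. Both were singled out after their values were seen. The 100 most abundant sequences held 14.4% of aligned reads on sucrose and 14.2% with nitrate.

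The comparison of nitrate with no nitrate addressed which transcripts differ in nodes fed sucrose when nitrate is supplied. Of the 27868 sequences, 516 (1.85%) were at least 2-fold higher with nitrate and 540 (1.94%) at least 2-fold lower, with a counting interval that excluded 1. The remaining 26812 did not pass the rule, and 79.5% of all tested sequences lay within 1.5-fold. Ratios of at least 4-fold, with 0.5 added to each count, were found for 30 higher and 45 lower sequences. Simulated libraries without any difference gave a mean of 179.9 higher and 182.4 lower sequences from counting error alone. The split between directions depended on scaling. Higher sequences made up 48.9% of those past the rule with TMM, 56.0% with plain totals or median-of-ratios, and 36.2% with upper-quartile scaling, which moved all log2 ratios down by 0.12 against plain totals.

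**Figure D1:**
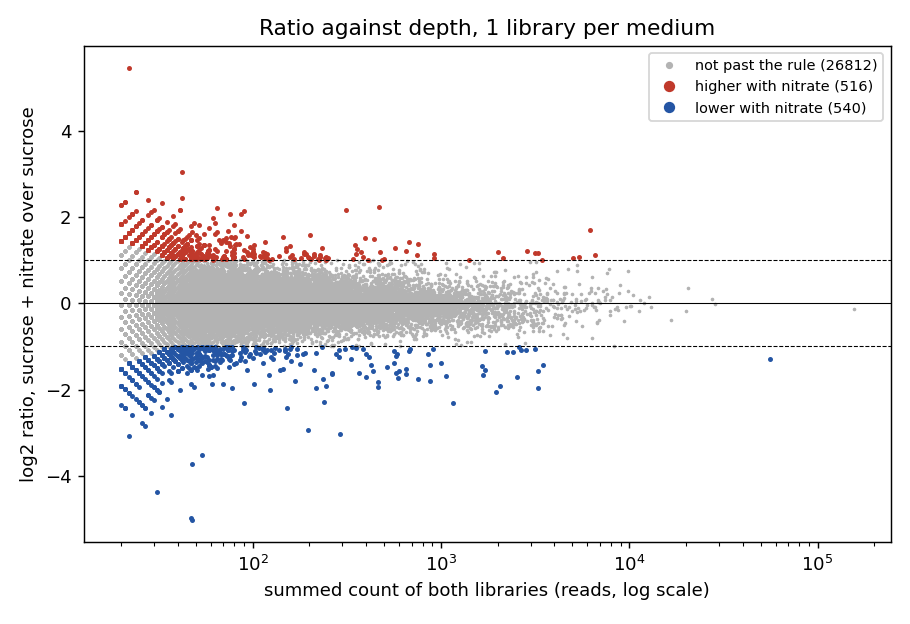
Log2 ratio of the nitrate over the sucrose library for each of the 27868 tested sequences (y axis) against the summed count of both libraries (x axis, log scale), with dashed lines at 2-fold. Red points are the 516 sequences called higher with nitrate and blue points the 540 called lower, and most of both lie at low counts.

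Well counted sequences stood apart by more than counting error, while simulation gave a sizeable part of the calls among thinly counted ones. Between 20 and 49 summed counts, 337 sequences were higher and 328 lower, 665 in all, against a mean of 322.6 in all, over both directions, in simulated unchanged libraries. From 200 counts upward, 46 of 6460 sequences were higher and 63 lower, and simulated libraries gave 0 in each of the bins from 200 counts upward. The interquartile range of log2 ratios was 0.78 at 20 to 49 counts, where simulation gave 0.69. It was 0.35 at 500 to 999 counts, where simulation gave 0.15, and 0.41 at 1000 counts or more, where simulation gave 0.09. Spreads of separate sources do not simply add. The difference between observed and simulated ranges therefore does not show whether the excess spread depends on depth. This excess spread holds any effect of nitrate together with any difference between pools of nodes or library preparations.

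**Figure D2:**
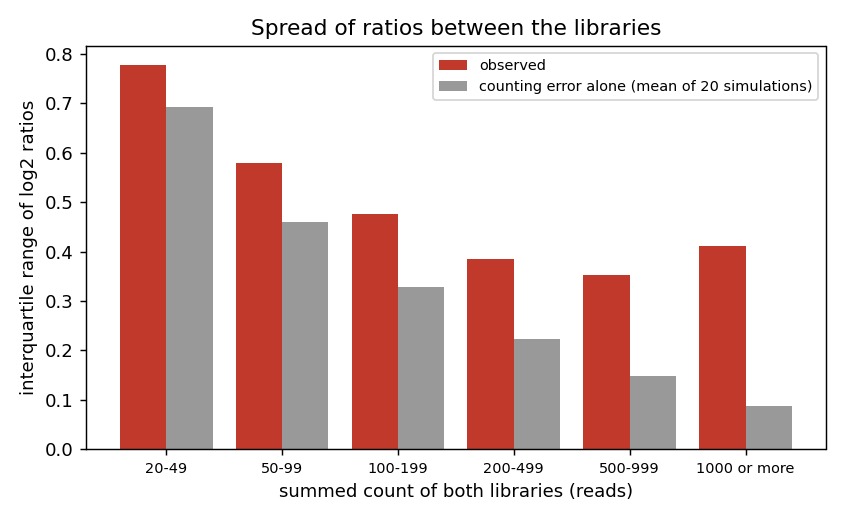
Interquartile range of log2 ratios between the nitrate and the sucrose library (y axis) in 6 bins of summed count (x axis, reads). Red bars are observed values and grey bars the mean of 20 simulations with counting error alone. They stand at 0.78 and 0.69 in the least counted bin, and at 0.41 and 0.09 in the most counted bin. Spreads do not simply add, so the gap between bars does not show whether excess spread depends on depth.

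By the naming rule, sequence Rosa_BI_20160929_035707 (1029 bases) ranked first among those higher with nitrate. It had 0 counts on sucrose and 22 with nitrate, 7.14-fold higher when the sucrose count is set at the floor of 3. The exact interval, which also carries the counting error of the 22 reads, started at 5.33-fold. Sequence Rosa_BI_20160929_009443 (1969 bases) ranked second, with 80 counts on sucrose and 391 with nitrate, or 24.0 and 117.2 CPM. Its ratio, with 0.5 added to each count, was 4.74-fold (counting interval 3.73 to 6.13).

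Sequence Rosa_BI_20160929_039285 (782 bases) ranked first among those lower with nitrate, with 47 counts on sucrose and 1 with nitrate. Its scaled ratio of sucrose over nitrate was 48.3 without the added 0.5 and 32.5 with it (counting interval 8.25 to 1946). Sequence Rosa_BI_20160929_027048 (1330 bases) ranked second, with 46 counts on sucrose and 1 with nitrate, a ratio of 47.2 without the added 0.5 and 31.8 with it (8.06 to 1906). The level with nitrate rests on 1 read in both cases, so the size of the difference is loosely bounded. On both sides, the sequences named by identifier were ranked by these same counts among all tested sequences. Their folds are therefore likely overstated, and their intervals do not cover this selection.

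Among sequences with a summed count of at least 1000, where counting error is smallest, 11 of 1033 were higher with nitrate and 20 lower. The largest fold among the higher ones was that of a sequence of 1679 bases, with 1415 counts on sucrose and 4756 with nitrate, a 3.27-fold difference (counting interval 3.08 to 3.48). The most deeply counted of the higher ones had 1608 bases, 2044 counts on sucrose and 4570 with nitrate, a 2.18-fold difference (2.07 to 2.30). On the lower side, a sequence of 4052 bases had 958 counts on sucrose and 198 with nitrate, 4.96-fold higher on sucrose (4.26 to 5.82). A sequence of 999 bases had 1573 and 385 counts, 4.19-fold higher on sucrose (3.75 to 4.70), and one of 920 bases had 2597 and 679 counts, 3.93-fold higher on sucrose (3.61 to 4.28). These 5 sequences were singled out after their values were seen.

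The sequences past the rule held a small part of the reads. The 540 lower sequences took 3.03% of aligned reads on sucrose and 1.20% with nitrate. Without the abundant sequence of 5824 bases these shares were 1.85% and 0.711%. The 516 higher sequences took 0.677% on sucrose and 1.65% with nitrate. Because the sequences were selected by the same counts, the direction of each difference in share is set by the rule, and its size is likely overstated.

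Log2 ratios shifted weakly with the length of the sequence, by 0.0309 per doubling of length over all tested sequences (bootstrap 95% interval 0.024 to 0.038). The Spearman rho with length was 0.061, and short, abundant sequences mostly lay lower in the nitrate library. The bootstrap resampled sequences as independent units, and its interval covers no spread between pools of nodes. RNA integrity of the pools, which can shift ratios by length, was not measured in the data analysed here. Among sequences with a summed count of at least 1000, the 179 of up to 1000 bases had a median log2 ratio of -0.29 (quartiles -0.52 and 0.01), and 73.7% of them lay below 0. The length classes were chosen after the data were seen. In the shortest class 9 sequences were called lower and 1 higher. The 447 sequences over 1000 and up to 2000 bases had a median of -0.08, with 6 called in each direction. The 407 sequences over 2000 bases had a median of 0.01, with 5 called lower and 4 higher. The median of the shortest class was -0.25 with plain totals and -0.36 with upper-quartile scaling, while that of the longest class was 0.04 and -0.07 and so changed sign.

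**Figure D3:**
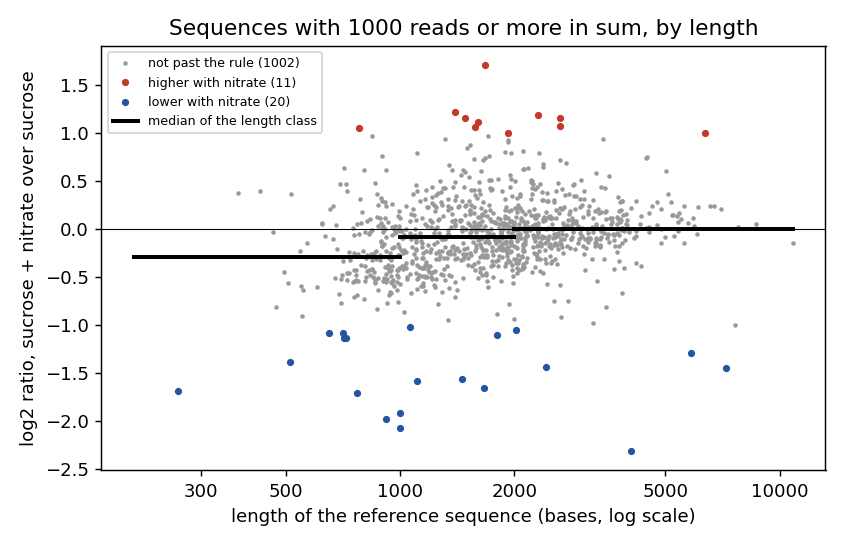
Log2 ratio of the nitrate over the sucrose library (y axis) against the length of the reference sequence (x axis, bases, log scale) for the 1033 sequences with a summed count of at least 1000. Black lines are medians of the 3 length classes, at -0.29 up to 1000 bases, -0.08 over 1000 and up to 2000, and 0.01 above 2000 with TMM scaling (the last is -0.07 with upper-quartile scaling), and coloured points are the 11 sequences called higher and the 20 called lower.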

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

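The number of sequences past the 2-fold rule depended on count filter, interval and threshold more than on scaling. Without a count filter, 908 sequences were higher and 884 lower, against 516 and 540 as reported. With a summed count of at least 100 these were 78 and 100. An interval with an error rate of 0.001 in place of 0.05 left 145 and 180, and requiring the whole 95% interval beyond 2-fold left 32 and 65. The 1.5-fold threshold gave 1186 and 1188, and the 4-fold threshold 30 and 45. These differences follow from the stricter or looser criteria themselves. The counts stayed within 1.5 times of those reported under the other scalings, 2 added to each count and centring by length, the last of which was chosen after seeing the data. Thinning of the deeper library was uninformative, since the aligned totals differed by 321 reads. Scaling changed which direction was more frequent, with 592 higher and 466 lower under plain totals and 391 and 688 under upper-quartile scaling. With TMM scaling the direction also turned without a count filter. The share of higher sequences fell to 33.0% with the whole 95% interval beyond 2-fold. The 4 sequences named by identifier kept their direction under the settings in which they were computed, and 3 of them fell below the filter of 100 counts. The size of those 3 depended on the count added, and with 2 in place of 0.5 the log2 ratio of Rosa_BI_20160929_035707 went from 5.45 to 3.55, that of Rosa_BI_20160929_039285 from -5.02 to -4.07 and that of Rosa_BI_20160929_027048 from -4.99 to -4.04. The settings fixed for gene lists and for asparaginase were not run, since the identifiers were not paired with names. No library could be left out, with 1 analysed per medium. No paired analysis was possible because 1 library of each medium was analysed. Depth limits the result first through the count filter, which 27868 of the 110110 sequences passed. Among tested sequences it does so mainly between 20 and 49 summed counts, where simulated counting error gave 322.6 calls over both directions beside 665 observed. Between 50 and 99 counts these were 39.05 and 213.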

Other observations

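The tests of read or insert length, of a bias alike at every depth, of RNA integrity and of length among neighbours were chosen after the values they rest on had been seen. The other tests were chosen before their result was seen, on patterns already noticed in the same data.

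Over 14596 pairs of sequences with directly neighbouring identifier numbers, the log2 ratios between media correlated across sequences with a Pearson r of 0.13 (bootstrap 95% interval 0.11 to 0.14) and a Spearman rho of 0.13, against 0.02 (-0.003 to 0.031) at a distance of 10 numbers. In the 1307 pairs where both had a summed count of at least 200, r was 0.372 (0.30 to 0.44) and rho 0.34, against 0.12 (0.04 to 0.19) at a distance of 10. The summed counts of direct neighbours also correlated (r = 0.19, against 0.03 at a distance of 10). This goes with the hypothesis that neighbouring numbers may hold parts or near copies of 1 gene. Length was not removed from the correlation of summed counts, so similar lengths of neighbours may add to it. Whether the hypothesis accounts for the r of 0.12 at a distance of 10 in deeply counted pairs was not tested. Over all pairs, shared length of neighbours is argued against as the whole source of the correlation of log2 ratios. With the length trend removed, the Pearson r was 0.126 (0.108 to 0.144), against 0.127 before. At 200 counts or more, length deciles held a share of 0.0276 of the variance of log2 ratios, beside the neighbour r of 0.372. That share leaves out differences in length within deciles, so it is not a strict limit. Called sequences were neighbours in 22 higher and 21 lower pairs, where random placement would give 5.00 and 5.48, so the 516 and 540 sequences are not all separate genes if the hypothesis holds.

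Log2 ratios rose slightly with length, by 0.0309 per doubling of length over all tested sequences (bootstrap 95% interval 0.024 to 0.038, Spearman rho 0.061). The rise was not even, with a median of -0.04 in each length decile up to 1382 bases and 0.04 in the longest decile. Scaling moves all ratios alike, so the sign of these medians depends on it, while the rise does not. The explanation by abundance, that longer sequences are also more deeply counted, is only partly answered. The rank correlation with length was above 0 in 5 of 5 bins of summed count. It rose from 0.017 in the least counted bin to 0.195 in the most counted. The least counted bin does not decide, since its slope interval includes 0. Nor does the most counted bin, which spans 236 to 155905 counts. In the bins between, at 0.033, 0.073 and 0.095, abundance is argued against as the whole source. No interval was computed for these correlations. An effect of read or insert length at the ends of short sequences stays open. The slope was 0.0399 (0.023 to 0.057) above 1500 bases, which does not decide, since such an effect can reach past that length. A bias set by the length of the listed sequence, alike at every depth, is argued against only if sequences are taken as independent. The slope was 0.0185 (-0.005 to 0.043) in the least counted bin, against 0.0817 (0.068 to 0.094) in the most counted one. That condition is not fully met, since log2 ratios of deeply counted direct neighbours correlated (r = 0.372). The intervals may therefore be too narrow. RNA integrity that differed between the pools stays open, because the positions of reads along the sequences are not used here, and so does a lower level of a set of short, abundant transcripts with nitrate, which was not tested.

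The 1056 sequences past the rule exceed the mean of 362.3 that counting error gave in simulated unchanged libraries. This difference does not decide on an effect of nitrate, since spread between pools of the same medium may also exceed counting error. That spread was not measured here. Spread between pools of nodes cannot be told apart from an effect of nitrate for any of the 1056 sequences, because 1 library of each medium was analysed here.

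The aligned totals of the libraries differed by 321 reads, against a Poisson standard deviation of the difference of 2583, while the totals including unaligned reads differed by 408811. That standard deviation assumes the same expected depth in both libraries, which is not given in the sources used here. The comparison therefore does not decide whether reads were removed.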
